A study of Mus musculus with 2 samples.

How the data were processed

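PolyA-selected RNA from whole-cell extracts of mouse bone marrow-derived macrophages was sequenced, per the labels, as 2 biological replicates of 1 treatment. The macrophages, which are cells grown from bone marrow in culture, were from C57BL/6J mice. Per the labels' description, they were pre-treated with Lipid A, the membrane anchor of bacterial lipopolysaccharide, at 100 ng/ml for 12 h, kept without it for 12 h, and stimulated again at 100 ng/ml for 300 min. The treatment field of the same labels names lipoprotein A, typed as a protein, and the labels do not settle which term is right. Both libraries carry the same donor identifier and separate biosample identifiers, so the spread between them may be smaller than the spread between animals. The series as used here holds no untreated, singly stimulated or washed-out sample, so no comparison between treatments was made and no gene was tested for a response.

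For each library the authors deposited a gene table and a transcript table with expected counts, per the file headers, and these tables are called the first quantification here. The README deposited with each sample gives the mm10 genome build and GENCODE release M21, and names a transcriptome alignment as the parent of these tables. The deposited TPM values of the first quantification are transcript abundances, scaled over every entry of the table to a fixed total, and the deposited FPKM values are scaled to length and depth, per the file headers. A further transcript table, called the second quantification, holds estimated counts and TPM made directly from the sequencing reads, per the README deposited with the sample. The names and versions of the aligner and of both quantifiers are not given in the sources used here. The column layouts are those that RSEM and kallisto write. Strand handling is also not given in the sources used here, so reads of overlapping or antisense genes may not have been told apart. All 55536 gene identifiers of the gene tables matched the GENCODE annotation, and 86 of them, on unplaced scaffolds, were not in the second quantification. The tables also held 26248 entries with numeric identifiers and a median length of 73 nt, 96 spike-in entries and 1 phiX174 entry, which stayed out of library sizes and of all gene results. The numeric entries had 0 counts, the spike-in entries had 0 counts in the first quantification, and phiX174 took 0.0631% and 0.0676% of all counts in replicates 1 and 2.

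Expected counts summed over genes came to 50503159 in replicate 1 and 46342331 in replicate 2. They were rounded to whole numbers before any count calculation. A gene with 0 counts could have had up to 3 counts, or 0.0594 CPM (counts scaled to the library total) in replicate 1 and 0.0647 in replicate 2. Exact 95% Clopper-Pearson intervals and these limits cover counting error only, since no molecular identifiers were used here. Levels are deposited gene TPM, given as the mean ± SD of both libraries. Log2 levels used a pseudocount of 1 TPM. Counts were scaled with TMM factors in edgeR 4.0.16 under R 4.3.3, after filterByExpr, which kept 12543 genes. Log2 CPM used a prior count of 0.5. The biological coefficient of variation was the square root of the common dispersion from estimateDisp with an intercept-only design. Alternative size factors came from DESeq2 1.42.0. Other steps ran in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

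The number of genes at least 2-fold apart between libraries was set beside 100 seeded binomial draws in which the libraries differed by counting noise alone. For each gene list, the median log2 ratio of replicate 2 over replicate 1 was taken over members that passed filterByExpr and had a mean count of 10 or more. With 1 group, filterByExpr asks for reads in both libraries, so members near 0 in one library, such as Gzmb, were dropped. The design set in advance named the mean count alone, and that wording was run as an alternative after seeing the data. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries only and is not a test of the treatment. Ratios between gene pairs were computed within each library. Transcript shares are a transcript's TPM as a percent of the summed transcript TPM of its gene. On counts simulated from the same genes and library sizes, coefficients of variation of 0.1 and 0.2 were fitted as 0.0996 over 12794 genes and 0.196 over 12734 genes for replicate 2 against replicate 1, where no gene was changed. With 200 genes changed they were fitted as 0.161 over 12763 genes and 0.234 over 12734 genes, so the fit includes genes that truly differ. With 200 genes changed by 2 on the log2 scale at a variation of 0.2, 100 of the 100 raised and 98 of the 100 lowered genes passed the 2-fold line, over 12734 genes, and so did 320 unchanged genes.

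Before the data were examined, 24 pathway lists, 10 cell type marker lists, 18 key genes, 12 gene pairs and 45 genes for transcript shares were fixed. The genes named are the key genes, the 15 highest genes outside mitochondrial, ribosomal protein and pseudogene classes, the 3 highest and the lowest member of each list, and the 10 genes furthest apart in each direction between libraries at a mean count of 100 or more. They also include the 10 genes furthest apart in each direction between the quantifications at 10 TPM or more, and leading transcripts with a share under 60%, with a different identity between quantifications, or of a key gene. A leading transcript that this rule takes is not reported here. Other genes are named as chosen after their values were seen. Where a symbol had more than 1 gene identifier, the protein-coding one was used. Alternatives covered the scaling, the count and TPM minimums, the prior count and pseudocount, FPKM, the second quantification, the 100 highest genes, and each library left out. A correction of log2 ratios for GC content and transcript length, by a loess fit with a span of 0.3, was also added after seeing the data.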

Results

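The data describe the polyA-selected transcriptome of mouse bone marrow-derived macrophages that had met Lipid A for 12 h, rested for 12 h and met it again for 300 min. There was 1 group with 2 biological replicates. Expected counts over genes totalled 50503159 in replicate 1 and 46342331 in replicate 2. The question the data address is which transcripts these twice-exposed macrophages held, at what level, and how far the replicates lay apart. All levels are TPM with the SD of the 2 libraries (n = 2), and coordinates are on mm10.

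Fth1, the ferritin heavy chain (chromosome 19, 9980598 to 9985098), stood at 48992 ± 1947 TPM, and Ftl1, the ferritin light chain, at 15286 ± 482 TPM. Ccl5, a chemokine for T cells and monocytes (chromosome 11, 83525778 to 83530518), reached 24312 ± 3177 TPM. Saa3, an acute-phase serum amyloid A gene (chromosome 7, 46711998 to 46715700), reached 21965 ± 3304 TPM. Other genes among the 15 highest were Tmsb4x at 15859 ± 5247 TPM, B2m at 13490 ± 78.6 TPM, Lyz2 at 10751 ± 649 TPM, H2-K1 at 8526 ± 865 TPM, Psap at 8115 ± 335 TPM, Ctsb at 8025 ± 1087 TPM, Cxcl10 at 6815 ± 242 TPM, Ctsd at 6332 ± 77.5 TPM and Actb at 6103 ± 1020 TPM. Apoe, the lipid carrier apolipoprotein E, differed more between libraries, at 7830 and 3436 TPM. The ribosomal RNA gene CT010467.1 took 17742 and 9696 TPM. In both libraries 10586 genes reached 1 TPM, of which 9781 were protein-coding, and 115 genes reached 1000 TPM. The 10 genes with the most counts, CT010467.1 among them, took 12.1% and 11.2% of the counts in replicates 1 and 2.

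Among the key inflammatory genes, Cxcl10 and Acod1 were high, Tnf and Il1b intermediate, and Il6 and Ifnb1 low. Acod1, which makes itaconate (chromosome 14, 103046977 to 103056573), stood at 3401 ± 340 TPM. Tnf (chromosome 17, 35199381 to 35202007) was at 718 TPM in replicate 1 and 384 TPM in replicate 2. Il1b, the interleukin-1 beta gene (chromosome 2, 129364570 to 129371139), was at 272 ± 4.12 TPM. Il6 (chromosome 5, 30013114 to 30019981) was at 22.8 ± 5.56 TPM. Il12b, the p40 subunit of interleukin-12, was at 50.9 and 128 TPM, and Nos2, the inducible nitric oxide synthase, at 49.6 and 120 TPM. The anti-inflammatory cytokine Il10 was at 38.1 ± 5.99 TPM and Ifnb1, the interferon beta gene, at 8.62 ± 3.83 TPM. Arg1, the arginase of alternatively activated macrophages, had 0 counts in replicate 1 and 3 counts in replicate 2. The feedback regulators were at 331 ± 43.4 TPM for Nfkbia, 103 ± 9.29 TPM for Tnfaip3, 76.3 ± 6.05 TPM for Irak3 and 54.7 ± 2.69 TPM for Socs3. Il1rn, the interleukin-1 receptor antagonist, was at 194 and 309 TPM, Tlr4 at 27.8 ± 4.77 TPM and Lcn2 at 72.6 ± 11.2 TPM.

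**Figure D1:**
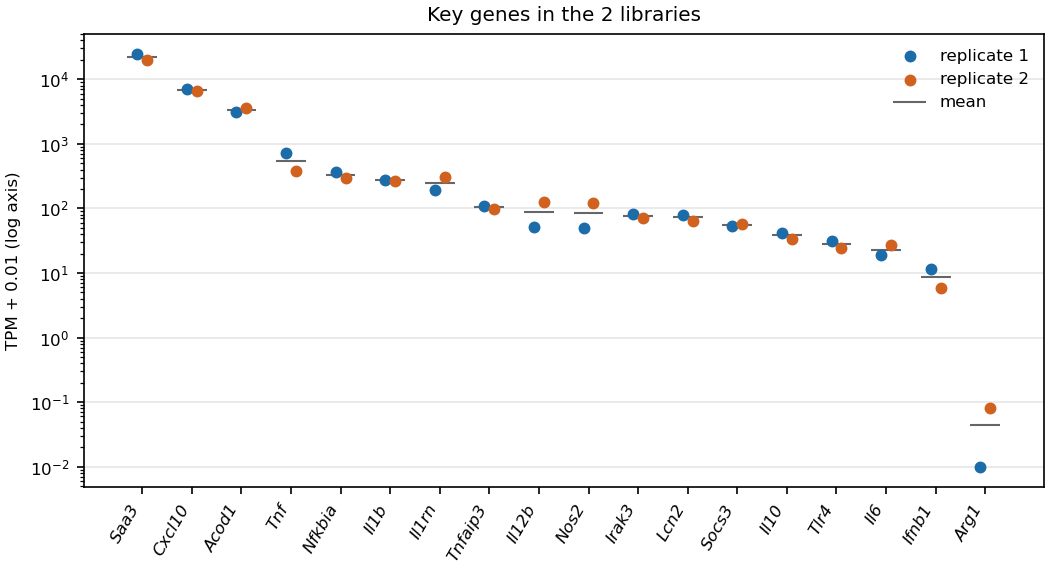
TPM plus 0.01 on a log axis for the 18 key genes in replicate 1 and replicate 2, with the mean as a line. Saa3 is highest at 21965 TPM, and Arg1 is lowest, with 0 counts in replicate 1 and 3 in replicate 2.

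Interferon-stimulated genes were abundant as a group. All 44 members reached 10 TPM in both libraries and 42 reached 100 TPM, with a list median of 594 TPM and a SD of 20.7 TPM between the library medians. After Cxcl10, the highest were Ifitm3 at 3912 ± 321 TPM and the antiviral gene Rsad2 at 3764 ± 13.2 TPM, and the lowest was Oas2 at 65.5 ± 11.7 TPM. Of the 16 type I and III interferon and receptor genes, 8 stayed under 1 TPM in both libraries and 6 of these had no read in either, while the highest members were the receptor and kinase genes Il10rb at 240 ± 0.940 TPM, Ifnar2 at 184 ± 11.3 TPM and Jak1 at 100 ± 19.5 TPM. Genes of MHC and antigen presentation had a median of 280 TPM, with 25 of 26 at 10 TPM or more and Ciita lowest at 4.47 ± 3.22 TPM.

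Of 25 chemokines, 12 reached 100 TPM in both libraries, and 5 stayed under 1 TPM in both. Ccl3, a chemokine for monocytes, stood at 2218 ± 942 TPM, and Cxcl12 was lowest at 0.0350 ± 0.0212 TPM. Of 20 proinflammatory cytokines, 12 reached 10 TPM and 6 stayed under 1 TPM. The highest after Tnf were Il15 at 316 ± 38.5 TPM and Ebi3 at 308 ± 15.2 TPM, and Lif was lowest at 0.0650 ± 0.0636 TPM. The negative regulators of Toll-like receptor signalling had 24 of 30 members at 10 TPM or more, led by Usp18 at 609 ± 138 TPM, Tnip3 at 457 ± 59.8 TPM and Atf3 at 361 ± 93.2 TPM. All 31 genes of the TLR4 receptor and its signalling reached 1 TPM, from Cd14 at 519 ± 242 TPM and Ikbke at 324 ± 60.2 TPM to Lbp at 1.56 ± 0.495 TPM. Other pattern recognition receptors had a median of 80.6 TPM, led by Clec4e at 1460 ± 326 TPM, with Tlr5 lowest at 0.0300 ± 0.0283 TPM. The inflammasome and cell death list had a median of 142 TPM, led by Bcl2a1b at 1156 ± 85.8 TPM, a value that may include reads of its near-identical paralogs.

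Genes often described as kept or raised on re-stimulation had a median of 200 TPM, and genes often described as reduced had a median of 27.5 TPM over the mean levels of their members, and of 16.5 and 23.2 TPM in replicates 1 and 2. The first list held Ccl5, Saa3 and Acod1 at its top and Mmp9 at 0.295 ± 0.12 TPM at its bottom. The list described as reduced held Ccl3, Ccl4 at 2127 ± 947 TPM and Tnf at its top, and Csf3 at 0.0850 ± 0.0778 TPM at its bottom. These medians are levels within 1 group, since no sample at another stage was analysed here. The M2 markers had a median of 1.35 TPM, with 10 of 20 under 1 TPM in both libraries, although Fcgr2b stood at 439 ± 47.0 TPM and Tgm2 at 167 ± 17.1 TPM.

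The lysosome and phagocytosis list had a median of 507 TPM and cell cycle genes one of 5.14 TPM. Oxidative phosphorylation and TCA cycle genes had a median of 93.6 TPM, and Atp5b led them at 628 ± 37.3 TPM. Glycolysis and hypoxia genes had a median of 91.7 TPM, led by Gapdh at 1137 ± 133 TPM. The nitric oxide, itaconate and redox list had a median of 53.5 TPM, and lipid efflux and liver X receptor targets one of 52.4 TPM. Cholesterol synthesis genes had a median of 22.9 TPM with Msmo1 highest at 93.8 ± 0.863 TPM. Prostaglandin and eicosanoid genes had a median of 18.0 TPM with Alox5ap at 179 ± 2.15 TPM, and heat shock and unfolded protein response genes one of 16.4 TPM with Hspa5 at 579 ± 107 TPM. Myeloid transcription factors had a median of 15.9 TPM with Spi1, the myeloid regulator PU.1, at 531 ± 39.9 TPM. AP-1 and immediate early genes had a median of 4.16 TPM, although Atf3 and Klf6 stood at 361 ± 93.2 and 246 ± 22.1 TPM. Housekeeping genes had a median of 293 TPM. The median reached 10 TPM in 21 of the 34 lists.

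All 17 macrophage markers reached 10 TPM in both libraries, with a median of 1222 TPM and Lyz2, Fcer1g at 3178 ± 418 TPM and C1qb at 2883 ± 485 TPM highest. The medians of the marker lists of other cells were 0.585 TPM for endothelial cells, 0.520 TPM for neutrophils (0.62 TPM in replicate 1 and 0.04 TPM in replicate 2), 0.295 TPM for osteoclasts, 0.210 TPM for dendritic cells, 0.150 TPM for fibroblasts and stroma, 0.0775 TPM for T and NK cells, 0.0375 TPM for erythroid cells and megakaryocytes, 0.0350 TPM for mast cells and basophils, and 0.010 TPM for B cells. In replicate 2 the medians for T and NK cells, erythroid cells and megakaryocytes, mast cells and basophils, and B cells were 0 TPM. In replicate 1 they were 0.155, 0.025, 0.05 and 0.02 TPM. Single members of the marker lists of other cells were abundant, such as Bst2, also counted among the interferon-stimulated genes, at 2087 ± 82.7 TPM, Pf4 at 186 ± 98.4 TPM and Csf3r at 89.7 ± 6.28 TPM.

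**Figure D2:**
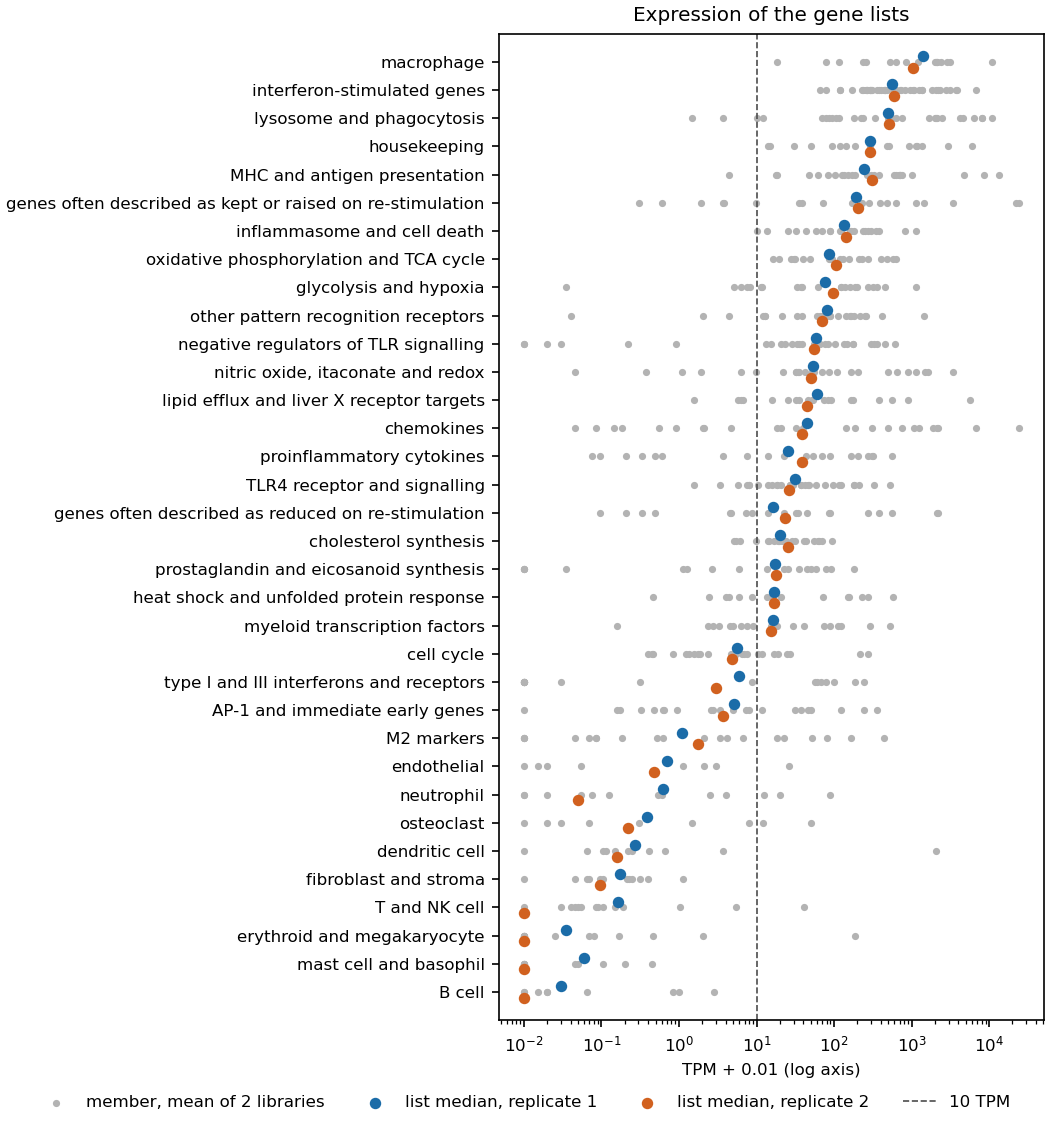
TPM plus 0.01 on a log axis for each member of the 34 gene lists (grey, mean of 2 libraries) and the list medians in replicate 1 and replicate 2. The medians are highest for macrophage markers, at 1402 and 1043 TPM, and 21 lists lie right of the line at 10 TPM in both libraries.

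Within each library, Cxcl10 exceeded Il6 by 8.18 ± 0.39 and Saa3 exceeded Il6 by 9.86 ± 0.56 on the log2 scale of TPM plus 1. Socs3 exceeded Il6 by 1.25 ± 0.27. Acod1 exceeded Nos2 by 5.44 ± 0.75. Arg1 over Nos2 was below 0 in both libraries, but with 0 and 3 counts of Arg1 its size was set by the pseudocount, at -6.24 with 1 TPM and -9.21 with 0.1 TPM. Irak2 and Irak3 exceeded Irak1, the kinase they modulate or oppose, by 2.06 ± 0.05 and 1.46 ± 0.05, and Ly96 exceeded its partner Tlr4 by 2.09 ± 0.02. Tnfaip3 over Tnf was -2.34 ± 0.51 and Lcn2 over Tnf was -2.85 ± 0.42. Il10 over Il12b was -0.26 in replicate 1 and -1.88 in replicate 2. Il1rn over Il1b was -0.50 in replicate 1 and 0.20 in replicate 2, so its direction was not the same in the libraries. The first gene was higher in both libraries in 7 of the 12 pairs.

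Single genes differed by up to several log2 units between the replicates. Among genes with a mean count of 100 or more, those furthest toward replicate 1 were Gm14308 at a log2 ratio of -5.78, the neutrophil calprotectin genes S100a9 (chromosome 3, 90692632 to 90695721) at -4.03 and S100a8 at -3.81, Dmpk at -3.22, Dmwd at -2.60, Iqgap3 at -2.25, Pclaf at -2.04, Gm21887 at -2.01, Zfp36l1 at -2.00 and Tmem26 at -1.97. Those furthest toward replicate 2 were Fam220a at 5.17 for one of 2 overlapping genes of that name, mt-Nd3 at 4.19, Klk1b11 at 2.67, the desaturase gene Scd1 at 2.55, Susd2 at 2.44, Gm49388 at 2.43, Gng4 at 2.31, Cdkn1c at 2.26, mt-Co3 at 2.23 and Lrrc63 at 2.17. Gm14308, Fam220a, Gm49388, Zfp36l1, Cdkn1c, mt-Nd3 and mt-Co3 had fractional counts, which mark reads shared with other genes, and their values are uncertain. The other Fam220a gene stood at -0.69. Of the key genes, Tnf had a log2 ratio of -0.91 and Ifnb1 one of -0.93, against 1.32 for Il12b and 1.26 for Nos2. The difference of the 2 libraries has no replicate check.

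Of 12543 genes, 528 lay 2-fold or more apart, 289 higher in replicate 2 and 239 higher in replicate 1. Counting noise alone gave 42.8 such genes on average over 100 draws, with a range of 28 to 60. That is not a measure of replicate spread: with a simulated coefficient of variation of 0.2 and no gene changed, 292 of 12734 genes lay past the same line for replicate 2 against replicate 1. The split of genes higher in replicates 2 and 1 was 314 to 412 in the second quantification, 130 to 66 at a mean count of 100 or more, and 2195 to 3286 without a filter on low counts. Within 1.5-fold lay 86.8% of the genes, and the biological coefficient of variation was 17.4%. Across 11306 genes, which are not independent replicates, log2 levels correlated with a Pearson r of 0.972 and a Spearman rho of 0.971. The chi-square statistic per degree of freedom was 69.8 over genes with 10 or more reads, so the libraries differed by more than sampling noise and both were counted.

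The chemokine median log2 ratio was -0.50, with 14 of 20 compared members higher in replicate 1, among them Ccl3 at -0.89 and Cxcl10 at -0.07. Ccl5, the most abundant member, stood at 0.28, and the summed chemokine level was 41631 TPM in replicate 1 and 41782 TPM in replicate 2. Lipid efflux genes had a median of -0.27, with Apoe at -1.19, but 7 of 20 members were higher in replicate 2, Scd1 among them. Prostaglandin genes had a median of -0.23 and macrophage markers one of -0.16. TLR4 signalling genes had a median of -0.12, but 12 of 31 were higher in replicate 2, with Cd14, the highest member, at 0.99, and their summed level was 2231 TPM in replicate 1 and 2444 TPM in replicate 2. Cell cycle genes had a median of -0.41, which lay inside the range of random lists when only genes with a mean count of 100 or more were used. The neutrophil list had a median of -2.46 over 4 members, but -0.64 over 6 in the second quantification, and the erythroid and megakaryocyte list one of -1.80 over 3. Toward replicate 2, the medians were 0.23 for heat shock and the unfolded protein response with 11 of 16 members higher in replicate 2, 0.19 for cholesterol synthesis with 15 of 20, 0.16 for glycolysis, 0.19 for genes described as kept on re-stimulation and 0.89 for 4 endothelial markers. Of these, Kdr stood at 1.91 and Vwf at 1.54, while Pecam1 differed less, with 203 and 221 counts, or 1.96 and 2.23 TPM. Cdh5, chosen after its values were seen, was lower in replicate 2 with 80 and 38 counts. The list described as kept was inside the random range at a mean count of 100 or more, with a median of 0.08, and at a mean count of 10 or more alone, with one of 0.09. These 13 of 31 lists lay outside the central 95% of 10000 matched random lists, where 1.55 lists of unrelated genes would by chance. Members of a list may vary together between cultures, and some genes are in several lists. The value of 1.55 therefore does not measure how many lists would lie outside between ordinary replicates. Interferon-stimulated genes lay inside the random range, at a median of 0.02, as did proinflammatory cytokines at 0.09 and negative regulators at -0.08.

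**Figure D3:**
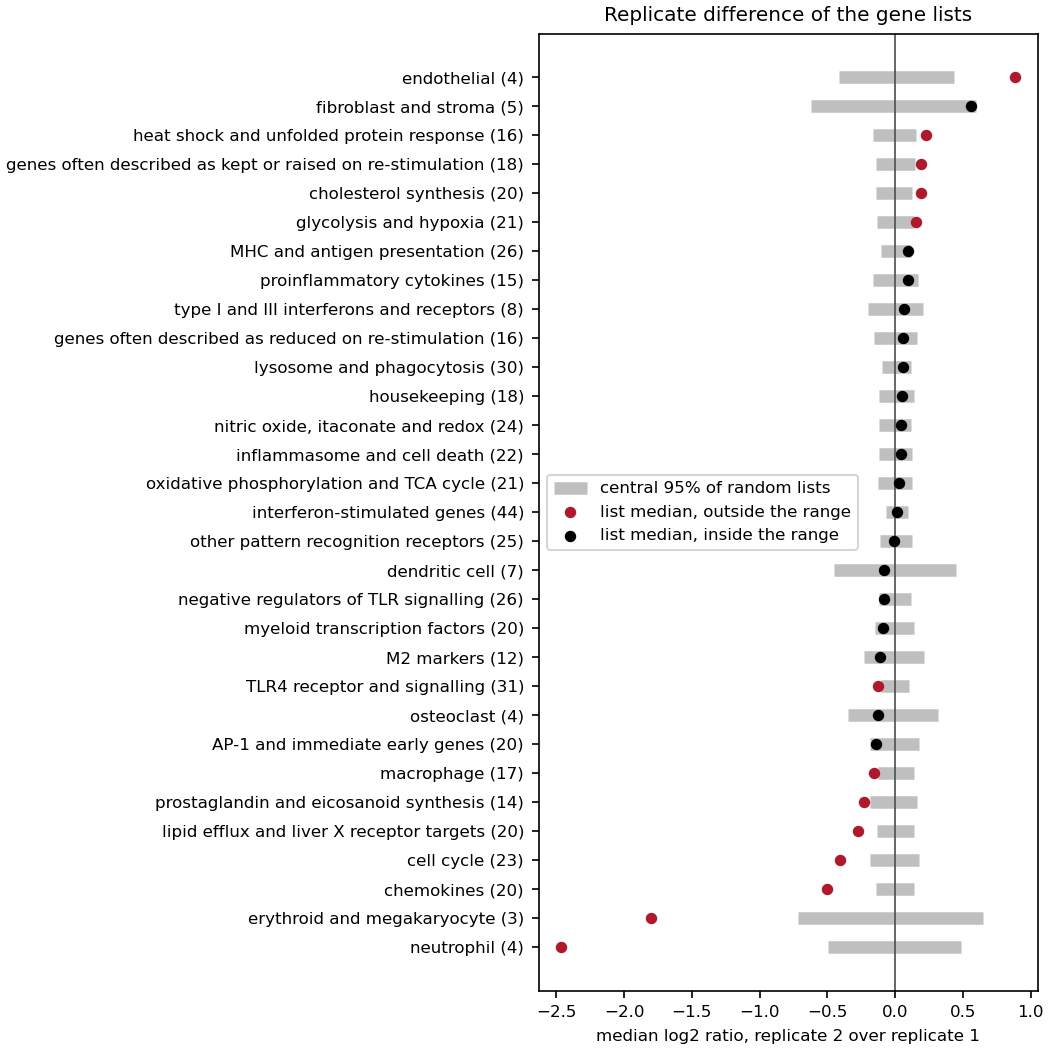
Median log2 ratio of replicate 2 over replicate 1 for 31 gene lists (points, members compared in brackets) and the central 95% of 10000 random lists matched on mean expression (bars). Red points mark the 13 lists outside that range, from -2.46 for neutrophil markers, a value of -0.64 in the second quantification, to 0.89 for endothelial markers.

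Most of the 45 genes chosen for transcript shares had 1 dominant transcript. The leading transcript held 60% or more of its gene in both libraries in 26 genes, those with only 1 annotated transcript included. Of the 42 genes with more than 1 transcript, 41 had the same leading transcript in both quantifications. Of the key genes, Tnf-201 held 99.9% ± 0.0290, Il1b-201 held 99.5% ± 0.201, Tlr4-201 held 99.6% ± 0.401, Cxcl10-201 held 98.2% ± 0.479, Il6-201 held 85.2% ± 3.45 and Il1rn-201 held 75.6% ± 0.0566 of their genes. Tnfaip3-202 held 42.5% ± 6.37 and was not the leading transcript in both libraries. Leading transcripts under 60% included Zbp1-202 at 55.4% ± 0.135, Cd44-207 at 56.1% ± 2.49, Irak1-206 at 45.2% ± 2.77 and Il15-202 at 41.0% ± 0.112. For Ptprc, which encodes the leukocyte antigen CD45, Ptprc-204 led the first quantification with 51.7% ± 3.13. In the second, Ptprc-203 and Ptprc-204 were nearly level, at 46.44% and 46.37%.

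The quantifications differed mainly in short and repeated genes. Of 12268 genes at 1 TPM or more in either, 1413 were 2-fold or more apart, 1091 of them higher in the second. The genes apart included 162 of 10179 protein-coding genes, 300 of 447 processed pseudogenes, 128 of 306 lincRNA genes and all 247 microRNA genes, beside other classes. Mir6236 stood at 0 TPM in the first quantification and 58815 TPM in the second, and Gm10222 at 917 TPM in the first and 0 TPM in the second. The second value of Mir6236 exceeds the 42976 TPM of Fth1 in the same quantification. With all 247 microRNA genes apart, neither value is a reliable level of this gene. Across genes with no minimum level, which are not independent replicates, the Pearson r was 0.975 and the Spearman rho 0.842. Across those at 1 TPM or more in either, they were 0.927 and 0.934.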

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

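Counts on phiX174, a bacteriophage genome often added to sequencing runs as a control, were outside the gene results and stood far above the limit that a count of 0 allows. They came to 31876 in replicate 1 and 31336 in replicate 2, or 0.0631% and 0.0676% of all counts. No explanation was tested, and the entry was left out of the library totals.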

How the results depend on the processing

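The correction for GC content and length and the lists at a mean count of 10 or more alone were added after seeing the data, and all other alternatives were planned. The number of genes 2-fold or more apart was 528, but 5481 without a filter on low counts, where counting noise alone gave 3607, and 196 at a mean count of 100 or more, where it gave 0. It was 420 with a prior count of 5 and 521 after the correction. The cause of the split of 314 to 412 in the second quantification was not tested. The other summary counts and the coefficient of variation moved by less than 1.5-fold under the alternatives run, while the chi-square statistic per degree of freedom, 69.8, ranged from 45.7 without the 100 highest genes to 90.3 over genes with 100 or more reads. At a mean count of 100 or more, 12 lists lay outside the random range, 10 of them shared. AP-1 genes at -0.43 and osteoclast markers at -0.51 joined, cell cycle genes at -0.10 and genes described as kept at 0.08 left, and the erythroid list had too few members. At a mean count of 10 or more alone, which keeps members near 0 in one library, 13 lists lay outside, 12 of them shared; genes described as kept left at 0.09, osteoclast markers joined at -0.50, and the neutrophil median was -3.80 over 7 members. After the correction, MHC and antigen presentation genes joined at 0.16, for 14 lists. Of the single list levels under the alternatives, 112 moved by no more than the SD between libraries and 91 by more. FPKM, another unit, shifted the levels by a median of -0.46 on the log2 scale. Keeping only members at 1 TPM or more could not lower a median. Leaving out a library returned the median of the other library, from which the SD was itself computed. For both reasons the split does not measure stability alone. The Il1rn over Il1b ratio was -0.50 in replicate 1 and 0.20 in replicate 2, so it reversed when replicate 1 was left out. Why the libraries differed in this ratio was not tested. Leaving out a library gives no value for the spread or the list differences, which need both. No paired analysis was possible because there was only 1 group. Genes at or under 0.0647 CPM in replicate 2, such as Arg1, could not be measured at this depth.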

Other observations

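The tests of the lower macrophage share, the neutrophils and the nuclear copies below were chosen only after the result was seen, while those of GC content and of AU-rich sequence were set before their results were seen. The list of MHC and antigen presentation genes lay inside the random range between replicates, at a median log2 ratio of 0.10 with 18 of 26 members higher in replicate 2, and outside it after the correction for GC content and length, at 0.16. No list of MHC class II genes alone was tested. Among single members chosen after their values were seen, Cd74 was at 680 ± 274 TPM with a log2 ratio of 0.83, H2-Aa at 262 ± 97.2 TPM with 0.77, H2-Eb1 at 152 ± 47.9 TPM with 0.73, H2-Ab1 at 171 ± 53.9 TPM with 0.65 and their regulator Ciita at 4.47 TPM with 1.52. Complement C3 at 1.25, Cd40 at 0.76 and Lipg at 1.92 also lay toward replicate 2, while Cd36 at -1.68, Ccl12 at -1.40, Dusp2 at -1.27 and Fos at -1.01 lay toward replicate 1. Dmpk and Dmwd, neighbours on chromosome 7 between 19076227 and 19093821, were both higher in replicate 1, with 267 and 364 counts against 26 and 55. In TPM the difference of Dmpk was smaller, at 3.89 in replicate 1 and 1.25 in replicate 2, while Dmwd stood at 5.09 and 0.87.

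Some marker genes of other blood cells had reads in only 1 of the libraries. Of 13 T and NK cell markers with reads, 8 had reads in replicate 1 only and 0 in replicate 2 only. Gzmb had 84 counts against 1, Nkg7 8 against 0 and Ncr1 7 against 0. Of 11 neutrophil markers with reads 2, and of 7 B cell markers 3, had reads in replicate 1 only, and 0 of each in replicate 2 only. The basophil genes Prss34 and Mcpt8 had 13 and 4 counts against 0, whereas Kit in the same list had 15 against 66. Over all genes with reads, 2201 of 19730 were seen in replicate 1 only and 1246 in replicate 2 only, and the marker lists were not tested against this. These genes were chosen after their values were seen.

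S100a8 and S100a9 had 189 and 344 counts in replicate 1 and 12 and 19 in replicate 2. Neutrophils in replicate 1 are a candidate source. The other neutrophil markers without Csf3r, which macrophages express, summed to 677 counts against 196, a log2 ratio of -1.67 with a counting interval of -1.91 to -1.44. Of members chosen after their values were seen, Ngp with 172 counts against 2 and Ltf with 52 against 1 followed S100a8 and S100a9, whereas Camp, also in the list described as kept on re-stimulation, had 11 against 9, and Ly6g and Retnlg had 0 counts in both. Without Mmp8 the sum was 248 against 14, and a difference in the macrophages themselves stays open.

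For the 13 lists outside the random range, a trend with GC content and transcript length was argued against as the only cause, since all 13 stayed outside after the correction. TLR4 signalling genes did so only just, at percentile 2.47 against a limit of 2.5. The chemokine median moved from -0.50 to -0.42 and that of lipid efflux genes from -0.27 to -0.20, while macrophage markers moved from -0.16 to -0.20. A partial contribution therefore stays open. A lower share of macrophages in replicate 2 was tested as if it raised the markers of every other cell type alike. The neutrophil median was instead -2.46, with all 4 members lower, and -0.64 in the second quantification. The endothelial median of 0.89 lay the other way, but rests on Kdr and Vwf, with Cdh5 lower. A lower share could also come with a rise of some other cells and a fall of others, so the test cannot decide it. A candidate explanation that passed its test is that replicate 2 held fewer short-lived transcripts. No half-life was measured, so genes with 2 or more AU-rich nonamers in the 3' UTR stood in for them. Tnf had 5 copies but Il6 had 0. The 496 such genes outside all lists had a median log2 ratio of -0.048, below the range of -0.03 to 0.03 of random sets. That shift is small beside the chemokine median of -0.50 and says nothing of the lists higher in replicate 2, so most of the pattern stays open, and the design, with 1 group, gave no treatment difference to test as its cause.

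The mitochondrial genes mt-Nd3 and mt-Co3, with mt-Atp6 chosen after its values were seen, were higher in replicate 2, and reads shared with near-identical nuclear copies on chromosome 1 are a candidate explanation. For mt-Nd3 the sum with Gm28438, which holds 98.1% of its 31-mers, had a log2 ratio of 0.16 against 4.19 for the gene alone, as the copy went from 7676 counts in replicate 1 to 3366 in replicate 2 while mt-Nd3 had 285 and 4814. For mt-Co3 and mt-Atp6 the copies held 17.1 and 15.5 times the reads of the gene itself or more, so the sum follows the copies whatever the cause, and its value of -0.18 for mt-Co3 decides nothing. In the second quantification the log2 ratio of TPM was 2.27 for mt-Nd3, 0.69 for mt-Co3 and -0.11 for mt-Atp6. No biological explanation was tested.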
